A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

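Polyadenylated RNA of the fission yeast Schizosaccharomyces pombe was sequenced from 3 strains with 3 biological replicates each, grown to log phase at 30 °C in the rich medium YES. Per the labels' protocols, RNA was purified with hot acid phenol, libraries were made with a strand-preserving TruSeq mRNA kit, and paired-end reads were collected on a NovaSeq X Plus instrument. The groups, taken from titles and descriptions, were the wild-type strain Sp1 (WT), a strain labelled as a deletion of rsm1 marked with natMX, and a strain carrying the nup211-1435 allele together with an asp1 gene marked with kanMX. The titles give all 9 libraries as h-, the mating type whose cells use the M markers described below. The P markers are genes used by h+ cells. The labels give no batch or date. The mutant strains also differ from WT by their drug-resistance markers, so an effect of a marker cannot be separated from that of the mutation in these comparisons.

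The authors deposited a table of raw read counts for 6988 annotated features in the 9 libraries, with whole-number values that were not normalized. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools, HTSeq 0.10.0 and DESeq2 were used with genome build ASM294v2. The annotation and the strand setting of HTSeq are not given in the sources used here, so values of features that overlap on either strand are uncertain. The authors also deposited a table for each mutant against WT with log2 fold changes, their standard errors, p-values and adjusted p-values, whose column names per the file headers are those of DESeq2. In each mutant comparison of the authors, 41 features with 0 counts in all 9 libraries carried a p-value. The authors' model may therefore have held libraries or counts other than those analysed here. The authors' tables were used only to set their values beside those computed from the counts.

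Total counts ranged from 20.98 to 28.11 M per library, and a floor of 3 counts corresponded to 0.107 to 0.143 CPM (counts scaled to a common library total). These floors cover counting error only, since PCR copies were not marked. No pair of replicates agreed within sampling noise, because the chi-square statistic of their counts per degree of freedom lay between 2.8 and 11.9. Gene names were matched through the reference assembly ASM294v3, by systematic identifier for 6836 features and by synonym for 12, and 140 features had no match. That assembly was used only for names, gene order, exon length and overlaps between features, and no coordinates are given because the files use another build.

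Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept by filterByExpr (minimum count 10, minimum total count 15), which left 6227, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with robust dispersion and no covariate was fitted to all 9 libraries, and each pair of groups was compared with the two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all features tested, and a gene was called at an adjusted p under 0.05. Stated levels are means ± SD of TMM-scaled CPM over n = 3 libraries, and fold changes are log2 values with their standard error (SE). All adjusted p-values of single genes come from this test unless another is named. The steps were tested on simulated counts for 6182 genes. In the comparison of the libraries labelled rsm1 deletion with WT, 87.6% of genes changed 1.5-fold and 95% of those changed 2-fold were recovered. The shares were 92% and 96% for nup211-1435 against WT, and 91.8% and 96.4% for the comparison of the mutants. False calls made up 3.74%, 4.59% and 4.18% of calls in these 3 comparisons. In the first of them, 97 simulated genes changed 1.5-fold and 100 changed 2-fold, a far smaller share than was called in the data. These rates may therefore not hold for the real comparisons.

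Gene lists were fixed before the data were examined. They covered the phosphate-responsive PHO regulon and its upstream noncoding RNAs, phosphate and inositol pyrophosphate homeostasis, 3′-processing and termination factors, the nuclear pore, mRNA export, the nuclear exosome, meiotic targets of the RNA-elimination factor Mmi1, the core environmental stress response, heat shock chaperones, and iron, copper, zinc and thiamine genes. They also covered ribosomal proteins, ribosome biogenesis, mating genes with separate M and P mating type markers, sporulation, nitrogen and amino acid transport, glucose genes, adhesion, septum hydrolases, histones, G1/S targets of the transcription factor complex MBF, Tf2 retrotransposons, noncoding RNA classes and the mitochondrial genome. Lists of at least 5 measured members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists of each comparison. The tests were repeated with a correlation estimated from the data, and with fry, which tests whether the genes of a set move one way and does not compare them with other genes. Some members matched by symbol do other things than the list's name says. Within the 3′-processing list pap1 encodes an AP-1-like transcription factor and fip1 an iron permease. The export list's ptr2 encodes a peptide transporter and its thp1 a uracil DNA glycosylase, the chaperone list's ssp1 a protein kinase, the exosome list's mot1 a TATA-binding protein-associated factor, and the ribosome biogenesis list's mak1, mak2 and mak3 phosphorelay sensor kinases. The listed name prt1 belongs to a protein-coding gene and was left out of the noncoding PHO list, as was nc-pho84, which had no match. Some genes sit in several lists, such as pho1 among the Mmi1 targets and mei2 among both the Mmi1 targets and the mating genes. The nuclear pore list holds the targeted genes rsm1 and nup211, and the phosphate homeostasis list holds the marked asp1. They are included in the counts of these lists.

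Genes were named by a rule fixed before the data were examined. It took nup211, rsm1 and asp1, the PHO genes and RNAs, and for each mutant against WT the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in either group and no overlap between the groups' libraries. It also took up to 4 members with the smallest adjusted p from each list that was called by camera or had at least 3 called members, and, with the same limits on CPM and overlap, the 5 largest changes each way between the mutants and the 5 genes each way that changed most in both mutants. Genes named outside this rule are stated to have been chosen after their values were seen. To compare the responses of both mutants, 100 simulated sets of unchanged groups against the same WT libraries were drawn, because shared controls alone correlate the fold changes. Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, no count filter, a filter of at least 10 CPM in 3 libraries, fits of only the groups compared, protein-coding genes alone, a test against the 2-fold threshold, the replicate number as a block, and leaving out each library in turn. Scaling by total counts, a shared response over protein-coding genes alone, and list tests without each library were added after the data had been seen. Checks of gene order, length and the figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.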

Results

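The transcriptome of log-phase fission yeast was profiled as poly(A)+ RNA in 9 libraries from 3 strains, with 3 biological replicates of each. Rsm1 and Nup211 are subunits of the nuclear basket of the pore complex, and the series asked how they influence RNA 3′-processing and transcription termination. Depth was 25.3, 26.3 and 28.1 M counts in the WT libraries, 25.8, 24.4 and 20.98 M in the libraries labelled rsm1 deletion, and 24.6, 25.1 and 27.2 M in the nup211-1435 libraries. The biological coefficient of variation was 3.95%, and of 6988 features 300 had no count in any library. On the leading principal component, which held 59.6% of the variance, the WT libraries lay between -28.2 and -26.7 and the mutant libraries between 10.7 and 17.2. The next component, with 25.5%, separated the libraries labelled rsm1 deletion from the nup211-1435 libraries.

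The targeted genes were examined first. The gene rsm1 (SPCC1753.05) was present in every library. It had 36.7 ± 0.4 CPM in WT, 31.8 ± 1.25 in the libraries labelled rsm1 deletion and 44.1 ± 0.93 in nup211-1435 (SD, n = 3 each). The fall by 0.21 (log2, SE 0.05, adjusted p = 0.00113) amounted to 13.3%. This is less than the loss of a whole gene would give, but the counts cover parts that a deletion may keep. The counts do not settle the label, and for that reason the strain is named by its label throughout. With scaling by total counts, chosen after the data had been seen, the log2 fold change of rsm1 was -0.06 with an adjusted p of 0.251, and the call was lost. The coding part made up 891 of 2575 nt of annotated exon, and 99.8% of the exon was overlapped by features on the opposite strand, so counts from outside the deleted part check nothing. The gene nup211 (SPCC162.08c) rose from 180 ± 10.5 CPM in WT to 249 ± 16.8 in the libraries labelled rsm1 deletion (0.47, SE 0.05) and to 267 ± 8.23 in nup211-1435 (0.57, SE 0.05), and a count over the gene does not show the allele. The gene asp1 (SPCC1672.06c), an inositol pyrophosphate kinase whose locus carries kanMX in the nup211-1435 strain, rose by 0.19 (SE 0.03) and by 0.60 (SE 0.03), from 131 ± 2.28 CPM to 149 ± 5.41 and 199 ± 2.13.

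The comparison of the libraries labelled rsm1 deletion with WT asked which transcripts change without this basket subunit, as far as the label holds. The acid phosphatase gene pho1 fell from 1225 ± 70.6 CPM to 263 ± 18.7 (log2 fold change -2.22, SE 0.05, adjusted p = 3.14e-12), and the phosphate transporter gene pho84 fell from 1509.6 ± 52.2 to 765 ± 34.0 (-0.98, SE 0.04, adjusted p = 1.46e-10). The glycerophosphodiester transporter gene tgp1 stood at 24.2 ± 1.54 and 23.4 ± 0.774 CPM (-0.04, SE 0.08, adjusted p = 0.624). All 3 noncoding RNAs transcribed upstream of these genes rose. The RNA prt2, upstream of pho84, rose from 26.9 ± 1.49 to 134 ± 2.96 CPM (2.31, SE 0.07), nc-pho1 from 4.55 ± 0.525 to 18.3 ± 1.98 (2.01, SE 0.12), and nc-tgp1 from 26.7 ± 1.15 to 59.6 ± 0.496 (1.16, SE 0.06). In the reference annotation prt2 shares 1870 nt with pho84 and nc-pho1 shares 1413 nt with pho1 on the same strand, while nc-tgp1 shares 77 nt with tgp1, so reads of these pairs may be assigned to either or dropped.

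In the same comparison, 4405 of 6227 genes were called (70.7%), of which 2284 rose and 2121 fell. At least 2-fold changes were found for 469 genes, with 295 rises and 174 falls. The heme-binding protein gene shu1 rose from 0.601 ± 0.00952 to 40.1 ± 7.88 CPM (6.05, SE 0.23, adjusted p = 7.52e-10), the siderophore-iron transporter gene str3 from 0.896 ± 0.789 to 54.2 ± 15.8 (5.88, SE 0.45), its relative str1 from 28.5 ± 14.6 to 382 ± 47.8 (3.73, SE 0.31), and the ferroxidase gene fio1 by 2.94 (SE 0.19). The glutathione S-transferase gene gst2 rose from 138 ± 6.89 to 1165 ± 80.9 CPM (3.08, SE 0.05) and the sulfiredoxin gene srx1 by 2.98 (SE 0.17). Among genes with at least 10 CPM in either group, the 10 largest rises also included SPAPB1A11.05 (3.45), SPCC18B5.02c (3.31), SPBC23G7.10c (2.96) and SPCC663.08c (2.92). Among such genes the largest falls besides pho1 were those of the transcription factor gene grt1, from 12.2 ± 1.38 to 1.09 ± 0.101 CPM (-3.49, SE 0.15), the phenazine biosynthesis family gene aes1 (-2.53, SE 0.14), SPAC227.17c (-2.21, SE 0.05) and SPCC330.03c (-2.21, SE 0.17). They were followed by SPNCRNA.291 (-2.06), SPNCRNA.1487 (-2.03), SPCP20C8.02c (-1.92), SPNCRNA.1096 (-1.87) and the cell surface glycoprotein gene pfl9 (-1.84).

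Among the fixed lists in this comparison, ribosomal protein genes fell, with 137 of 141 down, none up and a median of -0.42 (camera adjusted p = 1.23e-29, adjusted p = 0.448 with an estimated correlation). Examples were rps2202 (-1.72, SE 0.05), rps1401 (-1.18, SE 0.04) and rpl402 (-0.58, SE 0.03), and near-identical paralogs make single ribosomal protein values uncertain. Of 33 core stress genes 27 rose and 2 fell (camera adjusted p = 1.45e-13, adjusted p = 0.272 with an estimated correlation), among them the efflux transporter gene bfr1 (1.54, SE 0.04), the nuclear envelope gene ish1 (1.56, SE 0.05) and the stress transcription factor gene atf1 (1.04, SE 0.04). Of 14 adhesion genes 11 rose and 2 fell (camera adjusted p = 6.75e-05, adjusted p = 0.272 with an estimated correlation), led by the transcription factor gene cbf12 (2.19, SE 0.07), with the kinase gene lkh1 (1.15, SE 0.04) and gsf1 (1.10, SE 0.04) beside it. Of 17 iron genes 13 rose and 3 fell (camera adjusted p = 0.00387, adjusted p = 0.499 with an estimated correlation), including php4, a subunit of the iron-responsive repressor (1.06, SE 0.06). Of 22 glucose genes 15 rose and 4 fell (camera adjusted p = 0.00949, adjusted p = 0.272 with an estimated correlation), such as the dihydroxyacetone kinase gene dak2 (1.48, SE 0.05) and the maltase gene agl1 (1.19, SE 0.07). Of 25 nitrogen and amino acid transport genes 14 rose and 5 fell (camera adjusted p = 0.039, adjusted p = 0.499 with an estimated correlation), such as isp7 (1.55, SE 0.05), while the arginine biosynthesis gene arg3 fell by 0.71 (SE 0.04). In refits chosen after the data had been seen, the call of the nitrogen list was lost without replicate 3 of the libraries labelled rsm1 deletion (0.0905) and without nup211-1435 replicate 1 (0.0534) or 3 (0.0596). The other lists tested had camera adjusted p-values from 0.101 to 0.869. Adjusted over the list alone, the same numbers of these 6 lists' members were called.

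Of 28 genes in the 3′-processing and termination list 13 rose and 7 fell in the libraries labelled rsm1 deletion. The cleavage factor subunit genes mpe1 (0.56, SE 0.04) and ysh1 (0.34, SE 0.03) rose and the helicase gene dbl8 fell (-0.39, SE 0.03), while the members fip1 (iron permease; 2.64, SE 0.18, chosen after its value was seen) and pap1 (AP-1-like factor; 0.80, SE 0.03) are not processing factors. Of 30 nuclear pore genes 15 rose and 9 fell, all by less than 2-fold, for example nup189 (0.42, SE 0.03) and nup124 (0.37, SE 0.03). These counts include rsm1 itself among the falls and nup211 among the rises. Of 25 mRNA export genes 9 rose and 7 fell, with the THO complex gene tho1 at 0.38 (SE 0.04), while the member thp1 (0.57, SE 0.04) encodes a uracil DNA glycosylase. Of 28 exosome and RNA elimination genes 7 rose and 14 fell, among them the nuclear exosome nuclease gene rrp6 (0.40, SE 0.03) and the gene red1 (-0.39, SE 0.04) and the exosome subunit gene cti1 (-0.43, SE 0.04). Of 17 phosphate homeostasis genes 10 rose and 3 fell. The transcription factor gene pho7 (0.96, SE 0.05) and the ubiquitin ligase gene pqr1 (0.62, SE 0.04) rose, and the vacuolar transporter chaperone gene nrf1 fell (-0.59, SE 0.04). Adjusted over the list alone, the counts of these lists were the same. Camera called none of them, with adjusted p-values from 0.101 to 0.805, and 70.7% of all genes tested were called in this comparison.

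**Figure D1:**
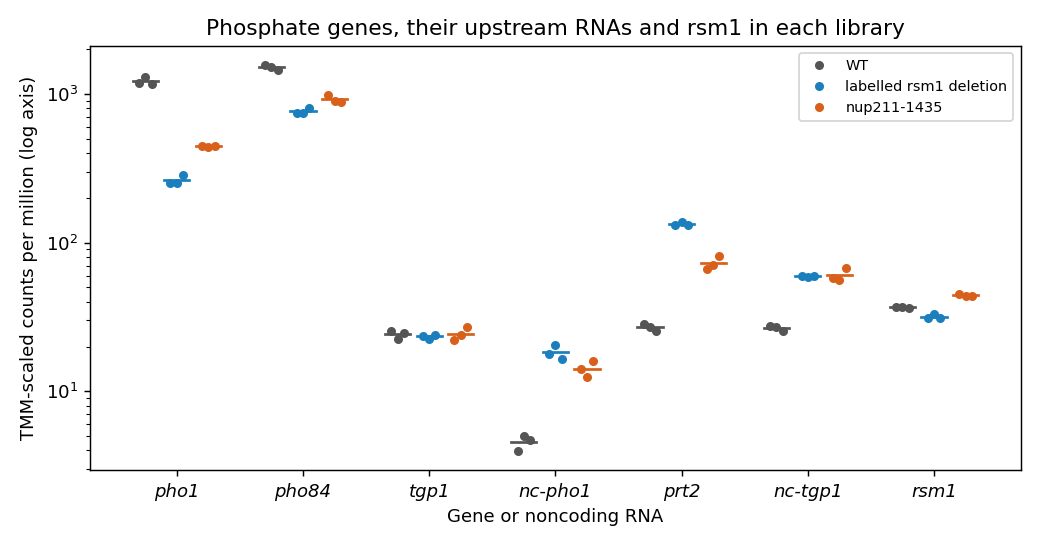
TMM-scaled CPM (log axis) of the phosphate genes, their upstream noncoding RNAs and rsm1 in each library, with WT in grey, libraries labelled rsm1 deletion in blue and nup211-1435 in orange. Points are single libraries and bars are means of n = 3. The gene pho1 had means of 1225, 263 and 444 and nc-pho1 means of 4.55, 18.3 and 14.2 in these groups.

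The comparison of nup211-1435 with WT asked the same question for the other basket subunit. The gene pho1 fell to 444 ± 5.45 CPM (-1.46, SE 0.05, adjusted p = 7.84e-11) and pho84 to 921 ± 48.7 (-0.71, SE 0.04, adjusted p = 3.62e-09), while tgp1 stood at 24.4 ± 2.57 CPM (0.01, SE 0.08, adjusted p = 0.874). The upstream RNAs nc-pho1 (1.64, SE 0.12), prt2 (1.43, SE 0.07) and nc-tgp1 (1.18, SE 0.06) rose. The same overlaps of these RNAs with their genes apply. Among genes with at least 10 CPM in either group, the 10 largest rises included those of gst2, to 2295 ± 63.0 CPM (4.06, SE 0.05, adjusted p = 3.93e-14), the dehydrogenase gene osr1 (4.27, SE 0.13), SPCC18B5.02c (4.78, SE 0.09), SPCC663.08c (4.39, SE 0.11), SPBC23G7.10c (2.76, SE 0.13), the catechol O-methyltransferase gene cmt2 (2.65, SE 0.10) and the spermine family transporter gene caf5 (2.64, SE 0.13).

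The largest rise in nup211-1435 was that of SPNCRNA.1144, from 0.801 ± 0.208 to 25.8 ± 1.32 CPM (5.0, SE 0.13). This RNA overlaps asp1 on the opposite strand over 1070 nt in the reference annotation, and the asp1 locus carries the kanMX marker in this strain only. The RNA SPNCRNA.1179 rose by 2.90 (SE 0.08), and the aldo/keto reductase family gene SPAC750.01, whose reads could be split between family members, by 3.57 (SE 0.53). Among genes with at least 10 CPM in either group, the largest falls were those of grt1 (-3.57, SE 0.15), the meiotic noncoding RNA omt3, from 38.03 ± 2.28 to 3.62 ± 0.715 CPM (-3.40, SE 0.15), aes1 (-2.93, SE 0.14), SPNCRNA.1487 (-2.90), SPNCRNA.863 (-2.84) and SPCC70.08c (-2.46). The M-factor pheromone precursor gene mfm2 fell from 45.1 ± 7.51 to 9.46 ± 0.364 CPM (-2.25, SE 0.12), and SPAC227.17c (-2.13), SPAC56F8.13 (-1.99) and SPNCRNA.1277 (-1.92) followed. In all, 4042 of 6227 genes were called (64.9%), with 2048 rises and 1994 falls, and 397 changed at least 2-fold, with 210 rises and 187 falls.

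Ribosomal protein genes also fell in nup211-1435, with 131 of 141 down, 2 up and a median of -0.37 (camera adjusted p = 7.48e-27, adjusted p = 0.565 with an estimated correlation). Examples were rps2202 (-1.61, SE 0.05), rpp202 (-1.53, SE 0.04) and rps1401 (-1.21, SE 0.04). Of 33 core stress genes 22 rose, or 23 adjusted over the list alone, and 3 fell (camera adjusted p = 1.68e-12, adjusted p = 0.565 with an estimated correlation). The efflux transporter gene bfr1 rose by 2.26 (SE 0.04), the pyridoxal reductase gene plr1 by 2.08 (SE 0.05) and ish1 by 1.20 (SE 0.05). Of 27 mating genes 15 fell and 7 rose (camera adjusted p = 0.0421, adjusted p = 0.565 with an estimated correlation). The meiosis regulator gene mei2 fell from 66.8 ± 3.15 to 17.8 ± 1.24 CPM (-1.91, SE 0.05), the mating MAP kinase gene spk1 by 1.27 (SE 0.08) and its cascade's adaptor gene ste4 by 1.02 (SE 0.07). In refits chosen after the data had been seen, without replicate 1 or 3 of the libraries labelled rsm1 deletion or without nup211-1435 replicate 3, the adjusted p of the mating list was 0.0516, 0.0656 and 0.0707, and its call ended. The other lists tested had camera adjusted p-values from 0.138 to 0.854.

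Of 28 genes in the 3′-processing list 16 rose and 8 fell in nup211-1435, including cft1 (0.45, SE 0.03) and ysh1 (0.37, SE 0.03). Of 30 nuclear pore genes 16 rose and 2 fell, for example nup189 (0.62, SE 0.03) and alm1 (0.62, SE 0.05), another basket component. The rises include the targeted genes nup211 and rsm1. Of 25 export genes 8 rose and 4 fell, among them the ubiquitin ligase gene ptr1 (1.36, SE 0.04), while the peptide transporter gene ptr2 fell by 1.88 (SE 0.08). Of 28 exosome genes 10 rose and 6 fell, with the helicase gene mtl1 at 0.43 (SE 0.03) and rrp6 at 0.43 (SE 0.03). Of 17 phosphate homeostasis genes 9 rose and 3 fell, with nrf1 at -0.76 (SE 0.04) and the phosphodiesterase gene gde1 at 0.43 (SE 0.04). The rises include asp1 (0.60), whose locus is marked in this strain. Of 17 iron genes 8 rose and 5 fell. The ferrichrome synthetase gene sib1 rose by 1.64 (SE 0.04), while the biotin transporter gene vht1 fell by 1.29 (SE 0.05). Both sib1 and ptr1 are longer than 9 kb, and all 10 protein-coding genes of that length rose in this strain. Adjusted over the list alone, the counts of these 6 lists were the same. Camera called none of them, with adjusted p-values from 0.143 to 0.57, and 64.9% of all genes tested were called in this comparison. With scaling by total counts, chosen after the data had been seen, camera called the nuclear pore list (adjusted p = 0.0265).

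**Figure D2:**
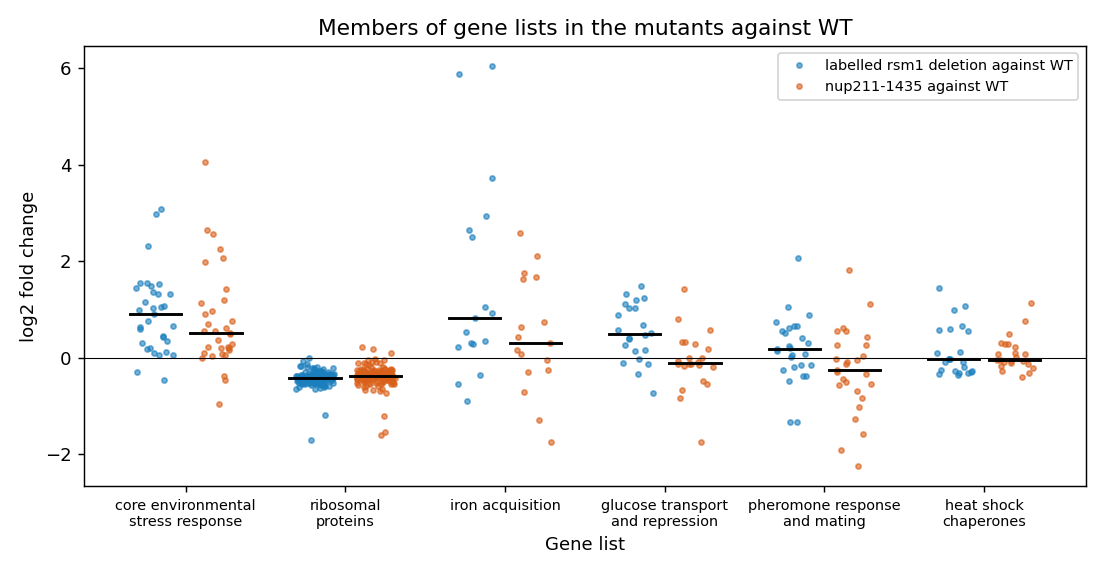
Log2 fold changes of each member of 6 gene lists, for the libraries labelled rsm1 deletion against WT in blue and nup211-1435 against WT in orange, with black bars at the medians. Each point is a gene. The ribosomal protein medians were -0.42 and -0.37, the stress medians 0.91 and 0.51 and the chaperone medians -0.03 and -0.04, and the signs of the ribosomal protein and stress medians were the same under every scaling tried.

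The remaining lists were described for both mutants against WT, with the libraries labelled rsm1 deletion named before nup211-1435. Camera called none of those it tested in the comparisons given, where 70.7% and 64.9% of all genes tested were called. Of 28 Mmi1 targets 7 rose and 6 fell, and 11 rose and 6 fell, with mcp7 at -0.84 (SE 0.09) and -1.22 (SE 0.09) and mbx1 at 0.57 (SE 0.04) and 0.34 (SE 0.05). Of 23 heat shock chaperone genes 9 rose and 11 fell, and 6 rose and 5 fell, with the disaggregase gene hsp104 up by 1.07 (SE 0.07) and 1.14 (SE 0.07). Of 11 copper and zinc genes 6 rose and 3 fell, and 3 rose and 5 fell, with the alcohol dehydrogenase gene adh4 at -1.11 (SE 0.04) and -1.16 (SE 0.04) and the zinc-responsive repressor gene loz1 at 1.07 (SE 0.05) and 0.52 (SE 0.05). Of 10 thiamine genes 3 rose and 5 fell, and none rose and 4 fell, with the acid phosphatase gene pho4 at -0.60 (SE 0.03) in both. Of 69 ribosome biogenesis genes 18 rose and 26 fell, and 29 rose and 12 fell, with the processome gene utp4 at -1.11 (SE 0.05) and -0.84 (SE 0.05). Of 27 mating genes 13 rose and 8 fell in the libraries labelled rsm1 deletion, where ste7 rose by 1.06 (SE 0.09).

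Of the 6 M mating type markers 2 rose and 3 fell, and 2 rose and 4 fell, with mfm2 at -1.34 (SE 0.11) and -2.25 (SE 0.12). Of the 4 P markers 2 rose and none fell, and none rose and 1 fell. That gene was sxa1 (-0.25), and the risen genes were map3 (0.42) and map4 (0.89), all 3 chosen after their values were seen. Of 23 sporulation genes 12 rose and 4 fell, and 11 rose and 4 fell, with the kinase gene pit1 at 1.28 (SE 0.06) and 0.57 (SE 0.06). In nup211-1435, 9 of 25 nitrogen genes rose and 10 fell, with the oligopeptide transporter gene isp4 at -1.20 (SE 0.07), and 5 of 22 glucose genes rose and 8 fell, with the fructose-1,6-bisphosphatase gene fbp1 at 1.42 (SE 0.09). In the same strain 10 of 14 adhesion genes rose and 2 fell, the lower of them pfl7 at -3.25 (SE 0.24). Of 11 septum genes 3 rose and 6 fell, and 3 rose and 4 fell, with the GTPase-activating protein gene rga5 at 1.22 (SE 0.05) and 0.76 (SE 0.05). Of 11 histone genes 1 rose and 4 fell, and none rose and 6 fell, and of 17 MBF targets 6 rose and 8 fell, and 5 rose and 8 fell, with mik1 at -0.41 (SE 0.05) and -0.68 (SE 0.05).

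Noncoding features moved in both directions. Of 1147 annotated noncoding RNAs 291 rose and 325 fell in the libraries labelled rsm1 deletion, with SPNCRNA.1023 at 2.63 (SE 0.08), and 257 rose and 352 fell in nup211-1435. Of 37 snRNAs and snoRNAs 14 rose and 6 fell, and 19 rose and 4 fell, with snR30 up by 1.25 (SE 0.05) and 1.23 (SE 0.05). Of 24 tRNA and rRNA features 5 rose and 9 fell, and 6 rose and 9 fell, at levels such as 0.318 ± 0.129 CPM for SPRRNA.13 in WT. Of the 4 Tf2 retrotransposons with enough counts 1 fell in the libraries labelled rsm1 deletion, and 1 rose and 1 fell in nup211-1435, and their near-identical copies make these values uncertain. No mitochondrial feature had enough counts to be tested. Adjusted over the list alone, counts against WT differed in a few lists. In the libraries labelled rsm1 deletion, 6 Mmi1 targets rose, 5 sporulation genes fell, 280 noncoding RNAs rose and 312 fell, and 8 tRNA and rRNA features fell. In nup211-1435, 28 ribosome biogenesis genes rose and 11 fell, 251 noncoding RNAs rose and 339 fell, and 5 tRNA and rRNA features rose. Median, mean and camera direction differed in sign in some lists, none of them called by camera, among them the chaperone, Mmi1, septum and mRNA export lists.

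The direct comparison of nup211-1435 with the libraries labelled rsm1 deletion tested where the mutants differed. Among genes with at least 10 CPM in either group, shu1, str3, omt3, ght5 and ctr4 were lower in nup211-1435 by the largest folds. The heme-binding protein gene shu1 stood at 0.172 ± 0.123 against 40.1 ± 7.88 CPM (-7.79, SE 0.28, adjusted p = 2.86e-09), str3 at 2.92 ± 0.572 against 54.2 ± 15.8 (-4.21, SE 0.36), the glucose transporter gene ght5 at 72.3 ± 8.97 against 604.9 ± 35.03 (-3.07, SE 0.26) and the copper transporter gene ctr4 at 46.6 ± 15.1 against 292 ± 12.3 (-2.64, SE 0.35). The noncoding RNA omt3 was lower by -3.72 (SE 0.14). Higher in nup211-1435 were SPNCRNA.1144 (5.56, SE 0.14), the glycoprotein gene SPBPJ4664.02 (1.72, SE 0.05), mdn1, which encodes the ribosome assembly protein midasin, from 308 ± 19.1 to 984 ± 45.2 CPM (1.67, SE 0.06), the RNase P RNA gene rrk1 (1.79, SE 0.40) and SPAC750.01 (1.93, SE 0.47, adjusted p = 0.0145). Without replicate 2 of the libraries labelled rsm1 deletion, the value of SPAC750.01 was 1.68 with an adjusted p of 0.0514, and its call ended.

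Between the mutants 3128 genes were called (50.2%), with 1526 higher and 1602 lower in nup211-1435, and 181 differed at least 2-fold, with 54 higher and 127 lower. Mating genes were lower (17 of 27 lower and 2 higher, camera adjusted p = 1.45e-08), as were nitrogen genes (15 of 25 lower and 1 higher, 5.62e-08) and glucose genes (16 of 22 lower and 3 higher, 4.83e-07), each with an adjusted p = 0.0684 with an estimated correlation. Adhesion genes were lower (11 of 14 lower and 2 higher, camera adjusted p = 7.82e-06, adjusted p = 0.107 with an estimated correlation), as were iron genes (13 of 17 lower and 2 higher, camera adjusted p = 0.00126, adjusted p = 0.417 with an estimated correlation) and copper and zinc genes (6 of 11 lower and 1 higher, camera adjusted p = 0.0362, adjusted p = 0.29 with an estimated correlation). Ribosome biogenesis genes were higher (37 of 69 higher and 1 lower, camera adjusted p = 0.000208, adjusted p = 0.819 with an estimated correlation), as were exosome genes (15 of 28 higher and 4 lower, camera adjusted p = 0.0251, adjusted p = 0.607 with an estimated correlation). Adjusted over the list alone, 15 iron genes and 16 glucose genes were lower and 4 glucose genes higher, and the counts of the other 6 lists were the same. The copper and zinc call was lost without WT replicate 2 (0.0519) or replicate 3 of the libraries labelled rsm1 deletion (0.0642). The other lists had camera adjusted p-values from 0.0714, for ribosomal proteins (47 of 141 higher and 7 lower), to 0.984. Ribosomal proteins were called between the mutants without WT replicate 3 (0.0431), without replicate 1 (0.0465) or 3 (0.0348) of the libraries labelled rsm1 deletion and without nup211-1435 replicate 3 (0.00955). The upstream RNAs prt2 and nc-pho1 were lower in nup211-1435 by -0.88 and -0.37, and pho1 (0.76) and pho84 (0.27) were higher.

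**Figure D3:**
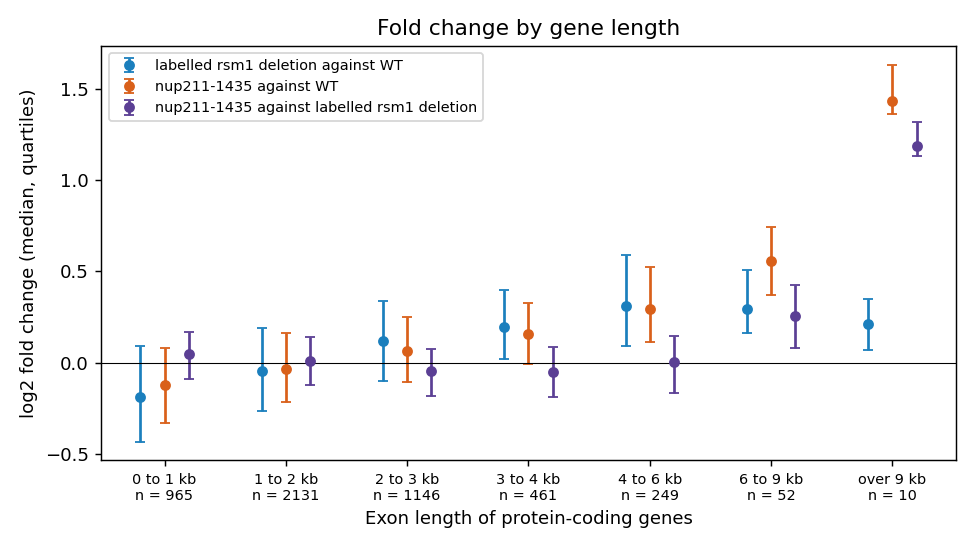
Median log2 fold change with quartiles by exon length of protein-coding genes in the 3 comparisons, in classes of 965, 2131, 1146, 461, 249, 52 and 10 genes from under 1 kb to over 9 kb. Above 9 kb the medians were 0.21 for the libraries labelled rsm1 deletion against WT, 1.43 for nup211-1435 against WT and 1.19 between the mutants.

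Fold changes against WT were correlated between the mutants across 6227 genes, which are not independent replicates (Pearson r = 0.747, Spearman rho = 0.773). Unchanged groups simulated against the same WT libraries gave a mean r of 0.502 and a highest r of 0.571. The covariance was 0.243 against a simulated 0.00677, a difference of 0.236. In both mutants 1639 genes rose, where independent lists would share 751, and 1547 fell, where independent lists would share 679, while 165 were called in opposite directions. In the simulations with shared controls a mean of 0.02 genes rose in both and 0.03 fell in both, with at most 1 in each case. No gene was changed in these simulations, so hardly any could be called, and independent lists take no account of the shared WT libraries. Neither number shows how many shared calls the common WT libraries give when many genes change. At least 2-fold, 143 rose in both against 9.95 for independent lists and 89 fell in both against 5.23. Among genes with at least 10 CPM in either group of each comparison, those that rose most in both were SPCC18B5.02c, gst2, SPCC663.08c, osr1 (2.77 and 4.27) and SPBC23G7.10c, and those that fell most were grt1, aes1, SPAC227.17c, SPNCRNA.1487 and the cysteine transporter gene SPBPB10D8.01 (-1.70 and -1.89). The 3 WT libraries cannot be divided into separate control sets of at least 2, so changes peculiar to these WT cultures would count as shared.

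Libraries of the compared groups did not overlap for 74.1% of genes between the libraries labelled rsm1 deletion and WT, for 67.8% between nup211-1435 and WT and for 59.0% between the mutants, where chance gives 10%. Scaling set the balance of rises and falls. With upper-quartile scaling 1694 genes rose and 2771 fell in the libraries labelled rsm1 deletion, and with total counts 3135 rose and 1394 fell, beside 2284 and 2121 with TMM. The corresponding counts in nup211-1435 were 1551 and 2569, and 3065 and 1243, beside 2048 and 1994. The median log2 fold change of all genes moved by -0.11 and 0.14 in the libraries labelled rsm1 deletion and by -0.08 and 0.13 in nup211-1435, so small changes are relative to the TMM scale. An adjusted p under 0.05 was given for 4396 genes in the authors' deposited table of the strain labelled rsm1 deletion, and for 4012 genes in that of nup211-1435. Of these, 4277 and 3884 were also called from the counts, all in the same direction. For pho1 the authors' deposited tables give -2.23 and -1.46, and for rsm1 in the strain labelled as its deletion the authors' deposited table gives -0.21.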

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

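The tests on the rsm1 counts and on the genes over 9 kb were chosen after the results were seen, and those on ribosomal protein genes and on other splits of the libraries before. Among genes that changed at least 2-fold in both mutants against WT, 5 moved in opposite directions, and the difference was tested directly between nup211-1435 and the libraries labelled rsm1 deletion. The copper transporter genes ctr4 and ctr5 differed by -2.64 (1.61 in the libraries labelled rsm1 deletion and -1.04 in nup211-1435) and -2.1 (1.07 and -1.03). The glucose transporter gene ght5 differed by -3.07 (1.32 and -1.75), the heme-binding protein gene shu1 by -7.79 (6.05 and -1.74) and SPCC1235.18, of unknown function, by -2.83 (1.37 and -1.46). The genes ctr5 and SPCC1235.18 were chosen after their values were seen. The WT spread was wide for ght5 (242 ± 84.8 CPM) and ctr4 (95.6 ± 38.7 CPM), and shu1 lay near the floor in WT and nup211-1435. No biological explanation was tested for these genes.

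Counts of rsm1 in the libraries labelled rsm1 deletion stayed near the WT level. The lowest rsm1 level over the 9 libraries was 31.0 CPM, but a library of a deletion strain could keep the counts of parts outside the deletion, so a swap of labels within the series stays open. Some values run the way the labels say. The libraries labelled rsm1 deletion were lowest, with 31.0 to 33.2 CPM beside 36.3 to 37.1 in WT and 43.5 to 45.2 in nup211-1435. A called fall was common in this comparison, with 2121 of 6227 genes. The call of rsm1 was lost with scaling by total counts (-0.06, adjusted p = 0.251), so its fall says little about the label. The RNA SPNCRNA.1144, which overlaps the marked asp1 locus, was higher in nup211-1435 than in either other group. Reads from parts outside the deletion or from overlapping genes could give such counts, since noncoding parts made up 65.4% of the annotated exon of rsm1. The counts fell by 13.3%, and with even coverage the loss of the whole coding part, 34.6% of that exon, would cost more. Coverage along the gene is not known. Overlapping features shared 0 nt with this exon on its own strand, so they could add reads only where strand was ignored. The overlapping TORC1 subunit gene tco89 and SPNCRNA.1204 were higher in these libraries by 0.38 and 0.87. Counts per gene do not show where reads lay, so these sources cannot be told apart from expression of the gene itself. Whether these libraries come from the strain on the label stays open, and no biological explanation was tested.

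Ribosomal protein genes fell in both mutants. Other genes of the same exon length fell less, by a difference of at least -0.28 in each mutant, and other genes of the same abundance fell less, by at least -0.16, with 0 of 10000 matched draws as low in either test. The highest ribosomal protein median over all scalings and both mutants was -0.23. These values argue against length alone, abundance alone or scaling alone as the whole cause. Genes were not matched on length and abundance at once, so a joint effect of both stays open. Reads shared between paralogs, drug markers and growth rate were not tested, and camera with an estimated correlation did not call the list.

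Genes with an exon length over 9 kb rose in nup211-1435. Scaling does not remove this, since the lowest median over 2 contrasts and 4 scalings was 1.18, and no single library made it, since the lowest median of a nup211-1435 library over the WT mean was 1.39. A bias that grows gradually with length could be a cause, because the medians of nup211-1435 against WT rose from each length class to the next. In the libraries labelled rsm1 deletion they did not, with 0.31 for 4 to 6 kb, 0.29 for 6 to 9 kb and 0.21 above. Between the mutants the median of genes of 4 to 6 kb was 0.00605, far below that of the genes over 9 kb. The 52 genes of 6 to 9 kb lay between, with a median of 0.26, 39 of them higher and 4 lower in nup211-1435. With 10 genes in the longest class, a gradual bias cannot be told apart from one acting on long genes alone. A library batch would be the same as the strain here, and no biological explanation was tested.

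For each comparison, the 6 libraries make 10 splits, too few for a share under 0.05. In the libraries labelled rsm1 deletion against WT, the real split called 4366 genes, 457 of them at least 2-fold. The real split called 3909 and 391 genes for nup211-1435 against WT, and 3242 and 183 between the mutants. In each case 1 of the 10 splits gave as many, the real one, and the highest of the others called 0 genes with the edgeR quasi-likelihood test.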

How the results depend on the processing

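Scaling by total counts, the shared response over protein-coding genes and list tests without single libraries were chosen after the data had been seen, and the other alternatives before. For the libraries labelled rsm1 deletion against WT, nup211-1435 against WT and nup211-1435 against the libraries labelled rsm1 deletion, in that order, at least 2-fold changes numbered 469, 397 and 181. They numbered 247, 185 and 85 with at least 10 CPM in 3 libraries, 264, 188 and 97 with only protein-coding genes, which both test fewer genes, and 213, 178 and 53 in a test against the 2-fold threshold, which is stricter by construction. Lists called by camera numbered 6, 3 and 8, and 0, 0 and 0 when camera estimated the correlation, where 3, 1 and 4 had an unadjusted p under 0.05. The list test fry called 16, 19 and 13. With total counts nup211-1435 had 5 lists against WT, since camera also called the nuclear pore (adjusted p = 0.0265) and annotated noncoding RNAs (0.0111). Noncoding RNAs were then also called in the libraries labelled rsm1 deletion (0.0348), and the cause was not tested. The correlation between the mutants, 0.747, was 0.762 over genes called in at least one contrast and 0.755 with at least 10 CPM, and the cause was not tested. Without single libraries it ranged from 0.724 to 0.745, and called genes ranged from 4095 to 4446, 3748 to 4033 and 2635 to 3225, 2-fold changes from 467 to 489, 397 to 420 and 172 to 191, and lists from 5 to 6, 2 to 3 and 7 to 9. Replicate numbers did not pair the mutant libraries with WT. Of 9 same-number pairs, 2 had a correlation of deviations from their group means above 0.1. Both were pairs of mutant libraries, replicates 1 (0.226) and replicates 3 (0.182), so a shared batch of these stays possible. As a block the numbers gave 4393, 4057 and 3133 genes, 468, 399 and 182 of them 2-fold. Of 4501 values for 253 results on named genes, 12 lost the call, 9 of them with total counts, 2 with upper-quartile scaling and 1 without replicate 2 of the libraries labelled rsm1 deletion. No gene called in the main fit reversed. The other 4489 values counted as unchanged. A change of sign of a gene not called in the main fit also counted as unchanged. Over all scalings the ribosomal protein median ranged from -0.53 to -0.28 in the libraries labelled rsm1 deletion and from -0.45 to -0.23 in nup211-1435, and the stress median from 0.80 to 1.06 and from 0.43 to 0.64. Rises made up 51.9% of calls in the libraries labelled rsm1 deletion, 37.9% with upper-quartile scaling and 69.2% with total counts, and 50.7%, 37.7% and 71.2% in nup211-1435. Depth limits values near the floor of 0.107 to 0.143 CPM.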

Other observations

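The tests on Pap1 targets and heat shock genes were chosen after the results were seen, and those on neighbouring noncoding RNAs and chromosome segments before. The longest genes of the genome were higher in nup211-1435. All 10 protein-coding genes over 9 kb rose, from 2.33-fold to 3.71-fold against WT, a set chosen after the values were seen. They encode the lipid transfer proteins vps1302 (1.89) and vps1301 (1.45), midasin (mdn1, 1.65), ferrichrome synthetase (sib1, 1.64), a glycoprotein (SPBPJ4664.02, 1.61), dynein heavy chain (dhc1, 1.42), the transcription cofactors tra2 (1.37) and tra1 (1.22), the ubiquitin ligase ptr1 (1.36) and the checkpoint kinase rad3 (1.23). In the libraries labelled rsm1 deletion 7 of the 10 rose, with a median of 0.21, and between the mutants all 10 were higher in nup211-1435, with a median of 1.19. The Spearman correlation of fold change with exon length over 5014 genes was 0.359 in the libraries labelled rsm1 deletion, 0.334 in nup211-1435 and -0.135 between the mutants.

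Targets of the oxidative stress transcription factor Pap1, listed after the data had been seen, had a median of 1.23 in the libraries labelled rsm1 deletion (11 of 14 rose and 2 fell) and of 2.03 in nup211-1435 (12 rose and 2 fell). The 20 other stress genes had medians of 0.70 and 0.23. The difference was 0.52 in the libraries labelled rsm1 deletion (one-sided permutation p = 0.138) and 1.80 in nup211-1435 (one-sided permutation p = 0.00011). The lists were drawn up with the fold changes in view and hold genes with large rises, such as osr1 and SPCC663.08c, so these p-values test nothing and a role of Pap1 stays open. A general heat-shock type stress also stays open. The higher of the 2 chaperone medians was -0.0328, but the members went both ways, with 9 of 23 risen and 11 fallen in the libraries labelled rsm1 deletion and 6 risen and 5 fallen in nup211-1435. The disaggregase gene hsp104 rose by 1.07 and 1.14, and the heat shock factor gene hsf1 by 0.55 and 0.28.

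Genes that follow, within 1000 nt on the same strand, a noncoding RNA that rose at least 2-fold were compared with genes that follow a noncoding RNA not called as risen, 42 with 328 in the libraries labelled rsm1 deletion and 30 with 346 in nup211-1435. The medians differed by -0.0945 (two-sided permutation p = 0.226) and -0.0441 (p = 0.484), so a general lowering of the next gene stays open. The run of 30 neighbouring genes with the largest absolute median was the first on chromosome II in the libraries labelled rsm1 deletion, at -0.53. This passes the bound of 0.5 set beforehand for a lost or gained segment. A lost or gained segment moves its genes one way, but 5 of these rose and 19 fell, from -3.49 to 2.08. A full loss would leave its genes without counts, yet the gene that fell furthest in both mutants, grt1, kept 1.09 and 1.02 CPM. The same run was the most extreme on this chromosome in nup211-1435, with a median of -0.37, 4 rises and 21 falls. A requirement that nearly all members move one way was added after this was seen. The rises beside the falls argue against a lost or gained segment that spans the whole run. A shorter segment that was gained, or lost in part of the cells, stays open.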
